A study of Bos taurus with 9 samples.

How the data were processed

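RNA of 9 samples was measured on single-colour bovine expression arrays, 1 array per sample. Per the labels' protocols, total RNA was extracted with trizol, and cDNA was primed with poly(T), amplified and labelled with biotin. Priming at the poly(A) tail and amplification favour the 3′ end of transcripts, so that the 3′ minus 5′ difference of control transcripts was computed for each array. The deposited values are on a log2 scale, as their range showed, and were made with RMA per the submitters' processing notes. RMA corrects the background, brings all arrays to 1 distribution of intensities by quantile normalization and summarises the probes of a set. The RMA version was not given in the sources used here. Quantile normalization assumes that arrays share a distribution, so that a change in total RNA per cell or a shift of most transcripts in 1 direction cannot be seen in these values. The deposited table held 24128 probe sets, of which 112 controls were left out of the tests, leaving 24016.

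Gene symbols came from the platform annotation, updated through gene identifiers in a RefSeq table of the assembly ARS-UCD2.0, which was used for names and neighbours of genes only. Of the probe sets tested, 13292 had 1 symbol, 86 had several and 10638 had none. Probe sets with several symbols or none were kept in the tests and not named. A gene was represented by the probe set of highest mean over all 9 arrays, which gave 9155 genes, of which 2913 had more than 1 probe set. SOX9 and other genes without a named probe set could not be reported.

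The groups were MSCs at day 0, MSCs at day 28 and chondrocytes at day 28, each with 3 arrays, and the comparisons were MSC_day28 minus MSC_day0, chondrocytes_day28 minus MSC_day28 and chondrocytes_day28 minus MSC_day0. A linear model with all 3 groups was fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, and p-values were adjusted by Benjamini-Hochberg over 24016 probe sets in each comparison, with calls at an adjusted p under 0.05. Standard errors are those of the moderated model. On simulated data for MSC_day28 minus MSC_day0, made with the spread of the arrays, 44 of 100 probe sets changed by 1 on the log2 scale and 89 of 100 changed by 2 were recovered, 12 of 145 calls were false, and an unchanged comparison had 0 calls. Only these probe sets were changed there, a far smaller share than was called in the data, and noise was independent between probe sets. The shares recovered therefore do not carry over to the real comparison.

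The labels number the donors, so that arrays with the same number came from the same calf. Across probe sets, deviations from the group means correlated from 0.108 to 0.412 between arrays of the same donor in different groups. Between arrays of different donors in different groups the range was -0.303 to 0.152. Deviations balance out within each group, so that these ranges are not independent of each other. The value of 0.412 was that of MSC_day28 replicate 3 with chondrocytes_day28 replicate 3. Both had low hybridisation controls, so that donor and hybridisation cannot be told apart for this pair. The model without the donor was used for the results, and the donor was added as a block as an alternative.

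The groups, the model, the 22 gene lists, the rule for named genes and the alternatives were chosen before the data were examined. Lists covered cartilage matrix, chondrogenic regulators, articular surface, hypertrophy, osteoblast, adipocyte, fibrous matrix, small leucine-rich proteoglycans, stromal surface, contractile cytoskeleton, cell cycle, TGF-beta and BMP signalling, matrix proteases, glycosaminoglycan synthesis, secretory pathway, hypoxia and glycolysis, inflammation, interferon response, blood cells, endothelium, skeletal muscle and ribosomal proteins. They were tested with camera at a preset correlation of 0.01, and p-values were adjusted over 66 tests. With a correlation estimated per list, 0 lists passed in any comparison. For each list, p-values of the members were also adjusted over the list alone. Named genes were, per comparison, the 6 largest rises and the 6 largest falls among calls with the same direction in all 3 donors, the member of each list with the smallest p, 2 more members where the list passed, and 9 fixed genes, of which SOX9 had no named probe set. Uncharacterised genes with LOC symbols were left out of the largest rises and falls. Further list members, the separate PRG4 and TPR probe sets and the interferon values per array were picked after their values had been seen.

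Overlaps of calls between comparisons that share arrays were set beside 50 simulations of unchanged groups and beside the overlap of independent lists. Positions of day 28 MSCs were computed as the change in MSCs divided by the difference between chondrocytes and day 0 MSCs. The alternatives were other scalings between arrays (centring on ribosomal protein genes or on the array median, cyclic loess), filters on low signal at the 25th percentile and the median, array weights, a trended and robust variance, fits of 2 groups alone, stricter thresholds, gene-level values, other list tests and leaving out each array or donor. For RNA quality, the slope of the cell cycle list's median per array on the 3′ minus 5′ difference, fitted within groups, and the difference between groups were taken with 95% intervals. Hybridisation controls were lower on 2 arrays, and a block for these arrays and a fit without them were added after the data had been seen. The lower quartile of values lay between 2.49 and 2.55 on each array, and no detection calls were used, so that differences between low values are compressed and uncertain.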

Results

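Gene expression was measured on 9 single-colour bovine arrays, 1 per sample, in articular chondrocytes and in marrow-derived mesenchymal stem cells (MSCs, the adherent stromal cells of bone marrow that can form cartilage, bone and fat) from 3 calves aged 3 to 6 months. Cells were embedded in agarose, a hydrogel that keeps them rounded and apart. MSCs were harvested right after embedding (day 0) or after 28 days in defined medium with 10 ng/mL of the cartilage-inducing growth factor TGF-beta3, and chondrocytes after the same 28 days. Each of the 3 groups held 3 arrays, 1 per calf. The arrays carried 24016 probe sets after removal of controls, of which 13292 had a single gene symbol, for 9155 genes. Values are on the deposited log2 scale, and differences are given with their standard error from limma (n = 3 arrays per group throughout) and a Benjamini-Hochberg adjusted p. The small number of arrays limits the precision.

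The groups separated clearly. The first principal component, with 56.8% of the variance, set day 0 MSCs apart from both day 28 groups, and the second, with 20.8%, set day 28 MSCs apart from chondrocytes. Correlations across probe sets, which are not independent replicates, ranged from 0.978 to 0.990 within groups, from 0.959 to 0.972 between day 28 MSCs and chondrocytes, and from 0.922 to 0.945 between day 0 and day 28 MSCs. No pair of arrays within a group was identical. Hybridisation controls were lower on 2 arrays, MSC_day28 replicate 3 and chondrocytes_day28 replicate 3: bioC averaged 8.80 there and 11.66 on the other 7. Fits without these 2 arrays rest on fewer arrays. They also leave donor 3 out of both day 28 groups, so that low controls and donor cannot be told apart by them. The difference in signal between the 3′ and 5′ ends of 5 control transcripts averaged 1.25 ± 0.30 (SD, n = 3) in day 0 MSCs, 1.86 ± 0.22 in day 28 MSCs and 1.87 ± 0.24 in chondrocytes. Day 0 MSCs differed from each day 28 group with a 2-sided exact permutation p of 0.1, the smallest that 3 arrays against 3 allow, and with 0.327 after adjustment over 18 such tests.

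**Figure D1:**
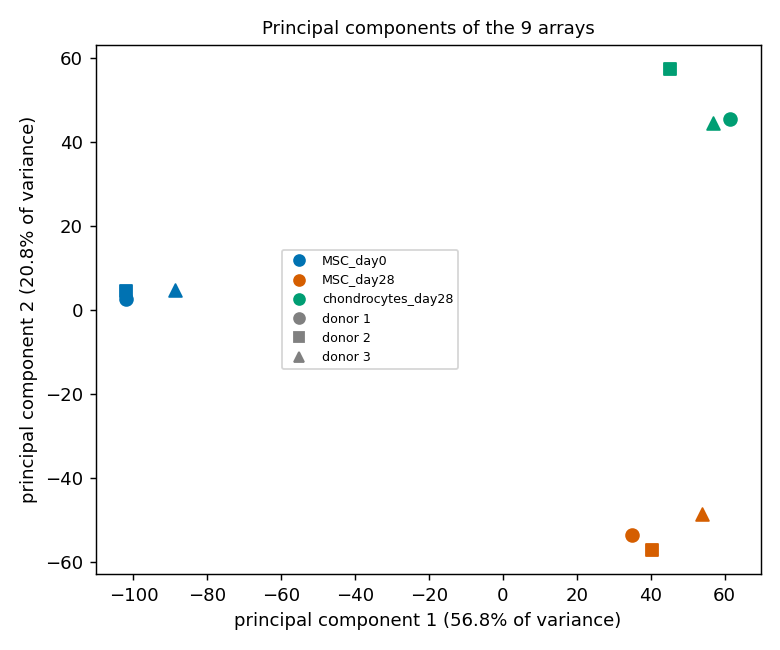
Each point is 1 array placed by its scores on the first 2 principal components of the deposited log2 values, with colour for the group and shape for the donor. Day 0 MSCs lie at the left, chondrocytes at the upper right and day 28 MSCs at the lower right, and the axes carry 56.8% and 20.8% of the variance.

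Over 28 days with TGF-beta3, 13 of 16 cartilage matrix genes rose in MSCs (list adjusted p = 4.46e-10, and adjusted p = 0.0898 with an estimated correlation). COMP, a glycoprotein that binds cartilage collagen, rose by 8.50 ± 0.18 (363-fold, adjusted p = 2.91e-08), ACAN, the core protein of the proteoglycan aggrecan, by 5.99 ± 0.40 (1.66e-05) and COL2A1, the main collagen of hyaline cartilage, by 5.96 ± 0.33 (6.26e-06). COL2A1 was the highest value on all 6 day 28 arrays, at the end of the scale, which may limit that value, though saturation was not tested. The other large rises were in SERPINA1 (8.47 ± 0.13), which encodes a secreted protease inhibitor, in the cartilage matrix gene CHAD (8.04 ± 0.23), in the collagen galactosyltransferase COLGALT2 (8.0 ± 0.26), in SMOC2 (7.21 ± 0.24) and in SHISAL2B (7.10 ± 0.36). Of the genes in the contractile and cell cycle lists, 13 of 16 and 19 of 24 fell (list adjusted p = 2.91e-08 and 8.48e-10, and adjusted p = 0.290 and 0.339 with an estimated correlation). The largest falls were in TTR, a thyroid hormone carrier (-7.85 ± 0.46), OLR1, a scavenger receptor (-6.62 ± 0.26), the transcription factor FOSB (-6.36 ± 0.18), the elongation factor EEF1A2 (-6.10 ± 0.49), CCN5 (-6.01 ± 0.46) and the chemokine GRO1 (-5.93 ± 0.73). The largest rises and falls were picked by the probe set of highest mean, among calls with the same direction in all 3 donors. Their agreement between donors was thus set by the rule. Uncharacterised genes with LOC symbols were not ranked, here and in the other comparisons.

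In this comparison 7256 of 24016 probe sets passed an adjusted p of 0.05, 3512 higher and 3744 lower at day 28, and 4231 of them changed at least 2-fold. Which direction held more calls depended on the scaling between arrays: 3834 were higher and 3252 lower when arrays were centred on ribosomal protein genes, and 3760 and 3427 with cyclic loess. By gene, with the probe set of highest mean standing for each, 1235 rose and 1919 fell among 9155. No group of MSCs cultured without TGF-beta3 was in the design, so that time in culture and medium could not be told apart.

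Of 16 measured cartilage matrix genes, 13 rose and 1 fell, with the same counts adjusted over the list alone and a median change of 3.07. The list test (limma camera, 66 tests) gave an adjusted p of 4.46e-10, and an adjusted p = 0.0898 with an estimated correlation. COL11A2 rose by 6.70 ± 0.19, COL9A1 by 5.41 ± 0.22 and the link protein HAPLN1 by 4.59 ± 0.16, while HAPLN3 fell by 1.84. MATN1 (-0.07 ± 0.17) and CRTAC1 (-0.43 ± 0.27) did not pass. Smaller rises were seen in CNMD, an inhibitor of vessel growth made by cartilage (1.67 ± 0.35, adjusted p = 0.00633, and 1.09 without donor 1), and in COL11A1 (1.24 ± 0.15). Of the 4 chondrogenic regulators named on the array, WWP2 rose by 4.48 ± 0.19, and GDF5, FGFR3 and NFIB did not pass (list adjusted p = 0.176). The regulator SOX9 had no named probe set.

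Among 12 genes linked to chondrocyte hypertrophy, 6 rose and none fell, over all genes and adjusted over the list alone (median 0.888, adjusted p = 0.0204, and adjusted p = 0.341 with an estimated correlation). The median was 1.75 with either filter on low signal, and 1.59 and 1.57 with the mean of probe sets and the set of largest SD. PTH1R, the receptor for parathyroid hormone and its related peptide, rose by 5.89 ± 0.49, the pyrophosphate-producing enzyme ENPP1 by 2.48 ± 0.35 and alkaline phosphatase, ALPL, by 5.95 ± 0.84. A second ALPL probe set was at 0.73 and did not pass. COL10A1, the collagen of hypertrophic cartilage, rose by 3.08 ± 1.00 (adjusted p = 0.045), and lost its call, at 3.46 ± 1.20, without the 2 arrays with low hybridisation controls (0.0746). It was at 1.65 without MSC_day28 replicate 1, and the call also ended with the batch block (0.0665), a trended and robust variance (0.0621) or a fit of 2 groups alone (0.0931). By the probe set of highest mean IBSP (0.10 ± 0.12), SPP1 (-0.56 ± 0.41), MMP13 (-1.84 ± 0.76) and IHH (0.30 ± 0.33) did not pass, whereas a second IBSP probe set rose by 4.19 ± 1.36 (adjusted p = 0.0442). Of 9 osteoblast genes, 2 rose, DLX5 and ALPL, and the list did not pass (adjusted p = 0.542).

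Contractile genes were lower at day 28: 13 of 16 fell, 14 adjusted over the list alone, with a median of -1.64. The list's adjusted p was 2.91e-08, and the adjusted p = 0.290 with an estimated correlation. Smooth muscle actin, ACTA2, fell by 4.98 ± 0.44, TAGLN by 4.75 ± 0.54, the tropomyosin TPM2 by 3.80 ± 0.27 and the actin crosslinker FLNA by 3.39 ± 0.22. Cell cycle genes fell in 19 of 24 cases, 22 adjusted over the list alone, with a median of -1.90 (adjusted p = 8.48e-10, and adjusted p = 0.339 with an estimated correlation). The mitotic cyclins CCNB1 and CCNB2 fell by 3.65 ± 0.29 and 4.29 ± 0.42, the mitotic kinase AURKB by 3.49 ± 0.27 and RRM2, a subunit of ribonucleotide reductase, by 3.86 ± 0.43. PLK1 (-0.04 ± 0.21) did not pass. Of 19 proteases and their inhibitors, 14 fell and 2 rose, 15 and 2 adjusted over the list alone (median -1.30, adjusted p = 0.000499, and adjusted p = 0.339 with an estimated correlation). The falls took in the aggrecanase ADAMTS5 (-2.25 ± 0.36), urokinase, PLAU (-3.59 ± 0.38), and also inhibitors, with TIMP1 at -1.51 ± 0.15. The urokinase receptor PLAUR rose by 2.31 ± 0.23 and TIMP4 by 2.26 ± 0.37, with 2 further TIMP4 probe sets, at 1.24 and 1.42, that did not pass. The 3′ to 5′ control difference given above was larger at day 28 in this comparison, beside all of these groups.

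The remaining lists did not pass in this comparison, and several held members that moved strongly in opposite directions. Fibrous matrix genes split into 5 that rose and 6 that fell of 17, with 5 and 7 adjusted over the list alone (adjusted p = 0.962). COL12A1 rose by 1.98 ± 0.13 and POSTN by 2.75 ± 0.55, while COL15A1 fell by 1.33 ± 0.19. COL1A1, the main collagen of bone and fibrous tissue, changed by -0.56 ± 0.18 (adjusted p = 0.044), a call that ended without the 2 arrays with low hybridisation controls (-0.56 ± 0.19, 0.0716), and its second probe set did not pass. The COL1A1 call also ended with centring on ribosomal protein genes (0.0802), cyclic loess (0.0819), array weights (0.0583) or a fit of 2 groups alone (0.0504). The median (-0.06) and mean (-0.02) of this list were negative, whereas the test pointed up. Among 8 small leucine-rich proteoglycans, 3 rose, with BGN at 1.95 ± 0.12, and 2 fell, OGN (-3.24 ± 0.43) and ASPN (-3.26 ± 0.41), with a list adjusted p of 0.795, a median of 0.05 and a mean of -0.36. Of 11 articular surface genes, 5 rose, among them the Wnt antagonist FRZB (6.55 ± 0.45), and 2 fell, or 1 without the 2 arrays with low controls (adjusted p = 0.127). PRG4, a lubricant of the joint surface, gave different results by probe set: the set of highest mean, at 0.30 ± 0.20, did not pass, another rose by 1.28 ± 0.26 (adjusted p = 0.0049), and the other 2, at -0.03 ± 0.30 and 0.99 ± 0.44, did not pass. The mean of the PRG4 sets passed, at 0.64 (adjusted p = 0.0246). Inflammatory genes rose in 6 and fell in 6 of 17 cases, 9 and 8 adjusted over the list alone: PTGS2 rose by 5.38 ± 0.70 and IL1R1 by 2.69 ± 0.19, while CXCL5 fell by 4.75 ± 0.63 and IL6 by 3.15 ± 0.55. That list had a median of 1.13, a mean of -0.13 and an upward test with an adjusted p of 0.693, and passed with a filter at the median signal (median 1.46, adjusted p = 0.0411).

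Of 22 genes of TGF-beta and BMP signalling, 6 rose and 5 fell (adjusted p = 0.427), or 3 fell without the 2 arrays with low controls, with PMEPA1, a feedback inhibitor of the pathway, at 3.06 ± 0.31, TGFBI at 1.91 ± 0.23 and BMP4 at -1.84 ± 0.17. Hypoxia and glycolysis genes rose in 7 and fell in 1 of 17 cases (adjusted p = 0.109), with the glucose transporter SLC2A1 at 2.07 ± 0.12 and EGLN3 at 4.29 ± 0.52. Secretory pathway genes rose in 5 and fell in 3 of 19 cases (0.538). PLOD1 rose by 2.14 ± 0.16, and its second probe set changed by -0.04. Of 15 glycosaminoglycan synthesis genes, 2 rose and 1 fell, or 3 and 5 adjusted over the list alone (0.871). CSGALNACT2 rose by 0.84 ± 0.17, and its second probe set, at -0.17, did not pass, nor did the mean of both (0.33, adjusted p = 0.104). Stromal surface markers fell in 3 and rose in 1 of 18 cases (0.229), with CXCL12 at -4.07 ± 0.56 and CD44 at -2.22 ± 0.34. With the donor as a block 6 of them fell, and without the 2 arrays with low controls 4, with 1 rise in either case. Among 12 adipocyte genes FABP4 fell by 5.31 ± 0.33 while LPL rose by 4.54 ± 0.36 and PLIN2 by 1.11 ± 0.22. For that list the median was 0.00213, the mean -0.05 and the adjusted p 0.871. 

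Markers of other cell types were measured alongside. Of 16 blood cell markers, TYROBP, AIF1, CD68 and CTSS fell (CTSS by 1.15 ± 0.16) and CSF1R rose by 1.62 ± 0.38 (list adjusted p = 0.217). Without the 2 arrays with low hybridisation controls, TYROBP (-2.37 ± 0.74, adjusted p = 0.0516), AIF1 (-2.19 ± 0.75, 0.0712), ERG (0.81 ± 0.28, 0.0733) and ACTA1 (-0.53 ± 0.18, 0.0635) did not pass, against -2.43 ± 0.62 and -2.08 ± 0.60 for TYROBP and AIF1 over all arrays. Of 12 endothelial markers, TEK (2.22 ± 0.29) and ERG (0.72 ± 0.23) rose (0.830), and of 12 skeletal muscle genes MYL11 rose by 0.76 ± 0.20, with a second probe set at 0.01 that did not pass, and ACTA1 fell by 0.46 ± 0.15 (0.871). None of 8 interferon-induced genes passed (median 0.720, list adjusted p = 0.538), and the median was -0.36 without MSC_day28 replicate 3. Without both arrays with low controls, 1 of these genes was called higher and 2 lower. RSAD2 was at 2.29 ± 0.82 (adjusted p = 0.0636), passed with the donor as a block (0.0191), and was at 1.12 without MSC_day28 replicate 3 (0.0347). None of 15 ribosomal protein genes passed (0.836), RPL10A at -0.30 ± 0.12 included.

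**Figure D2:**
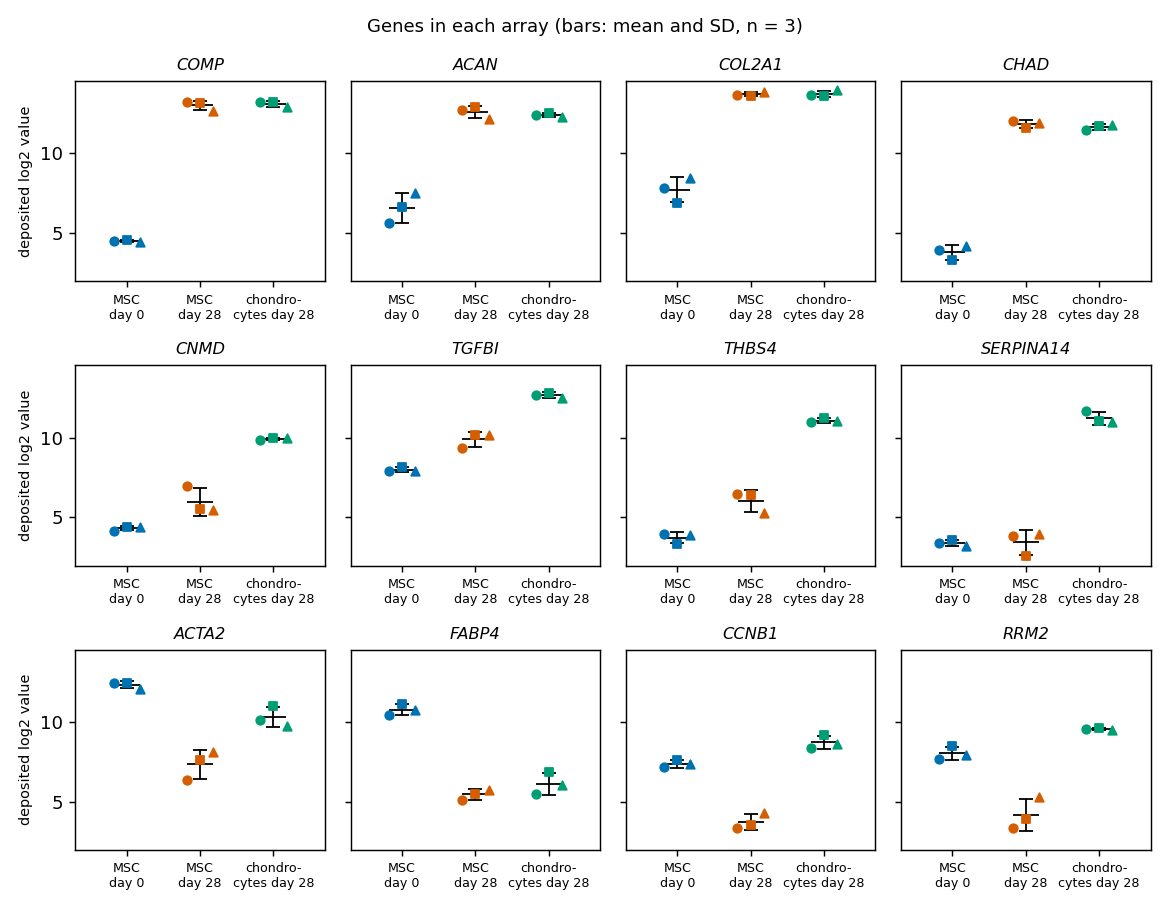
Deposited log2 values of 12 genes in each of 9 arrays, with the mean and SD (n = 3) as bars and donors 1, 2 and 3 as circles, squares and triangles. COMP, ACAN, COL2A1 and CHAD were high in both day 28 groups, CNMD, TGFBI, THBS4 and SERPINA14 were highest in chondrocytes, and CCNB1 and RRM2 were lowest in day 28 MSCs.

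After the same 28 days, 23 of 24 cell cycle genes were higher in chondrocytes than in MSCs of the same donors (list adjusted p = 2.16e-31, and adjusted p = 0.134 with an estimated correlation), and 14 of 16 cartilage matrix genes were not called (list adjusted p = 0.357). The difference, chondrocytes minus MSCs, was -0.19 ± 0.40 for ACAN (adjusted p = 0.850), 0.04 ± 0.33 for COL2A1 (0.969) and 0.10 ± 0.18 for COMP (0.816), none of which passed. The COL2A1 value, at 13.69 and 13.73, was the highest on each of these arrays. Its difference may thus be compressed, and it does not show that the transcript was alike in both groups. Saturation was not tested. The 3 other COL2A1 probe sets, from 0.39 to 0.54, did not pass. Chondrocytes had more CNMD (3.93 ± 0.35, adjusted p = 0.000214), more of the matricellular gene THBS4 (5.02 ± 0.32, 2.66e-05) and more of TGFBI, a collagen-binding matrix protein (2.74 ± 0.23, 0.000144). By the probe set of highest mean for each gene, the largest differences were in the serpin SERPINA14 (7.79 ± 0.35, 221-fold), PCLAF, a partner of the replication clamp (6.46 ± 0.19), and the neuropeptide GAL (6.09 ± 0.45). SHCBP1 (5.77 ± 0.23), the fatty acid carrier FABP3 (5.76 ± 0.26) and RRM2 (5.39 ± 0.43) followed. Other probe sets of PRG4 and TPR, given below, differed by up to 7.93. MSCs had more CCDC39, a gene of motile cilia (-4.22 ± 0.49), ANGPTL7 (-4.20 ± 0.44), the monocyte chemokine CCL2 (-3.70 ± 0.46), DDIT4L (-3.69 ± 0.55), the laminin receptor subunit ITGA7 (-3.56 ± 0.52, with 2 further probe sets at -1.01 and -0.65, of which 1 passed) and CD200 (-3.45 ± 0.45). Without donor 1 the calls of CCL2 (-3.64, adjusted p = 0.0532), DDIT4L (-3.63, 0.0832) and ITGA7 (-3.48, 0.0594) ended, at nearly the same differences and with fewer arrays.

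A total of 2482 probe sets passed, 1506 higher and 976 lower in chondrocytes, and 1475 of them differed at least 2-fold. By gene, 764 were higher and 440 lower. The split depended on the scaling between arrays: it was 2182 to 570 when arrays were centred on ribosomal protein genes, which moved the median of all probe sets by 0.16, and 1344 to 1359 when they were centred on the array median.

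Of 24 cell cycle genes, 23 were higher in chondrocytes, 24 adjusted over the list alone, none was lower, and the median difference was 3.53. The list had an adjusted p of 2.16e-31, and an adjusted p = 0.134 with an estimated correlation. CCNB1 was higher by 5.01 ± 0.29, AURKB by 4.67 ± 0.27 and the replicative helicase subunit MCM4 by 2.37 ± 0.14. UBE2C (2.16 ± 0.63) did not pass over all probe sets. Proteases and their inhibitors were higher in 10 of 19 cases and lower in none, over all genes and adjusted over the list alone (median 0.740, adjusted p = 2.65e-06, and adjusted p = 0.290 with an estimated correlation). PLAU was higher by 3.90 ± 0.38, the aggrecanase ADAMTS4 by 2.59 ± 0.70, MMP3 by 2.73 ± 0.47 (2 other probe sets, at 0.37 and 0.51, did not pass) and TIMP1 by 1.31 ± 0.15. CTSL was higher by 2.15 ± 0.18, at low signal (1.48 in MSCs and 3.62 in chondrocytes). The 2 arrays with low hybridisation controls lay in these groups, 1 in each, and without them the medians were 3.85 for the cell cycle and 0.728 for the proteases, of which 6 rather than 10 were higher, and ADAMTS4 did not pass (2.67 ± 0.65, 0.0521).

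Contractile genes were higher in 5 of 16 cases, 7 adjusted over the list alone, and lower in 1 (median 0.653, adjusted p = 0.00126, and adjusted p = 0.353 with an estimated correlation). ACTA2 was higher by 2.96 ± 0.44 and FLNA by 1.59 ± 0.22, with a second FLNA probe set at 0.17 that did not pass, whereas LMOD1 was lower by 1.72. Without the 2 arrays with low controls 3 contractile genes were higher, and without donor 2 the list's median was 0.354. Fibrous matrix genes were higher in 4 of 17 cases, 6 adjusted over the list alone (median 0.308, adjusted p = 0.00118, and adjusted p = 0.290 with an estimated correlation). The median was 0.532 without donor 1, 0.471 when arrays were centred on ribosomal protein genes and 0.474 with a filter at the median signal. These 4 were COL15A1 (2.83 ± 0.19), POSTN (2.60 ± 0.55), COL6A2 (1.28 ± 0.22) and COL6A1 (0.77 ± 0.16), the last with 2 further probe sets that did not pass and without a call when the 2 arrays with low controls were left out (0.78 ± 0.22, 0.0748), or with the mean of its probe sets (0.0962). COL1A1, at 0.47 ± 0.18, did not pass (adjusted p = 0.143). Of 17 hypoxia and glycolysis genes, ENO1 (0.61 ± 0.13), SLC2A1 (0.58 ± 0.12) and PGAM1 (0.72 ± 0.20) were higher, 5 adjusted over the list alone (median 0.378, adjusted p = 0.00266, and adjusted p = 0.353 with an estimated correlation). Without the 2 arrays with low controls SLC2A1 (0.61 ± 0.16, adjusted p = 0.0599) and PGAM1 (0.76 ± 0.26, 0.129) did not pass, which left 1 gene of the list as higher. PGAM1 also did not pass when arrays were centred on the array median (0.0627) or with a fit of 2 groups alone (0.0907). The list lost its call without donor 1 (median 0.323, adjusted p = 0.218) and without MSC_day28 replicate 1 alone (0.276, 0.0623).

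Among 8 small leucine-rich proteoglycans, OGN (3.31 ± 0.43) and OPTC (1.51 ± 0.30) were higher, 3 genes adjusted over the list alone (median 0.504, adjusted p = 0.0204, and adjusted p = 0.290 with an estimated correlation), and OMD, at 0.86 ± 0.25, did not pass over all genes (0.0621). OMD passed when arrays were centred on ribosomal protein genes (1.03, 0.0274), with cyclic loess (0.90, 0.0443), and in gene-level tests with the mean of probe sets (0.0474) or the set of highest mean (0.0492). Of 15 glycosaminoglycan synthesis genes, 5 were higher and 1 lower, 6 and 1 adjusted over the list alone (median 0.217, adjusted p = 0.0306, and adjusted p = 0.290 with an estimated correlation). UGDH, which makes UDP-glucuronate, was higher by 1.66 ± 0.19, UST by 1.36 ± 0.19 and BPNT2 by 1.05 ± 0.14, and CSGALNACT2 was lower by 0.71. Without the 2 arrays with low hybridisation controls, the adjusted p was 0.0556 for the proteoglycans and 0.0646 for glycosaminoglycan synthesis, with medians of 0.457 and 0.189, so neither list passed, nor did CSGALNACT2 (-0.55 ± 0.18, 0.115). With a filter at the median signal the proteoglycan list had a median of 0.06 and did not pass (0.202), and with one at the 25th percentile the median was 0.86 (0.0405). The glycosaminoglycan list also did not pass with the mean of probe sets (median 0.04, adjusted p = 0.0652), the set of largest SD (0.000777, 0.139), the set of highest mean (0.0699), centring on ribosomal protein genes (median 0.38, 0.0576), a filter at the 25th percentile (0.0527) or the batch block (0.0502), and its median was 0.575 with a filter at the median signal (0.0411).

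The cartilage matrix list did not pass in this comparison (median 0.07, adjusted p = 0.357), with CNMD and HAPLN3 (2.41 ± 0.40) higher and 14 of 16 genes not called. None of 12 hypertrophy genes passed (adjusted p = 0.918), COL10A1 at -2.36 ± 1.00 and TGM2 at 0.67 ± 0.24 included, and none of 9 osteoblast genes (0.686). Of 22 genes of TGF-beta and BMP signalling, 6 were higher, among them ID1 (2.51 ± 0.50), BAMBI (1.49 ± 0.26) and TGFB3 (1.39 ± 0.29), with a list adjusted p of 0.0754. NFIB, at 1.09 ± 0.45, did not pass (adjusted p = 0.170), and passed with the donor as a block (0.0384). In the inflammatory list TNFAIP6, a hyaluronan-binding protein (3.27 ± 0.34), and IL6 (2.34 ± 0.55) were higher and CCL2 and C3 (-2.37 ± 0.44) lower, and the list did not pass (0.564). IL6 (2.20 ± 0.72, 0.115) and C3 (-2.15 ± 0.56, 0.0619) lost their calls without the 2 arrays with low controls. Stromal surface markers were higher in 4 and lower in 3 of 18 cases (0.962). ITGA5 was higher by 1.67 ± 0.23, but its 2 other probe sets, at -0.47 and 0.28, did not pass, nor did the mean of the 3 (0.49, adjusted p = 0.102). P4HA3, a collagen prolyl hydroxylase subunit, was higher by 1.37 ± 0.19 in the secretory list (0.0692), where 3 genes were higher and 1 lower of 19.

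PRG4, the lubricating proteoglycan of the joint surface, gave different results by probe set. The set of highest mean differed by -0.01 ± 0.20 between chondrocytes and day 28 MSCs (adjusted p = 0.985). The 3 other PRG4 sets were higher in chondrocytes by 4.80 ± 0.26, 7.34 ± 0.30 and 7.88 ± 0.44. TPR, its neighbour in the annotation, had 1 probe set at 7.93 ± 0.48 and the other at -0.25 ± 0.36. The first shares the stem of its probe set name with the 3 higher PRG4 sets and may measure PRG4 transcripts. Of 11 articular surface genes, THBS4 and VIT (0.98 ± 0.16) were higher by the probe set of highest mean, and the list did not pass (0.239). With the mean of probe sets for each gene the list passed (adjusted p = 0.0488).

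Other cell types' markers also differed in places. Of 16 blood cell markers, CSF1R (1.60 ± 0.38), S100A8 (3.55 ± 0.78) and S100A9 (2.09 ± 0.38) were higher in chondrocytes and CTSS was lower by 1.12 (list adjusted p = 0.145). Without the 2 arrays with low controls S100A8 did not pass (3.47 ± 1.07, 0.0996). TIE1 (0.93 ± 0.23) was the endothelial marker that passed, of 12 (0.952), and did not pass when arrays were centred on the array median (0.0514) or with a fit of 2 groups alone (0.0815), in a list with a median of -0.03 and a mean of 0.06. Of 12 skeletal muscle genes, 2 were higher, with TNNI2 at 1.67 ± 0.29, and 3 lower (0.962), or 1 and 1 without the 2 arrays with low controls. Adipocyte genes held LIPE as higher (1.02 ± 0.23, with 3 other probe sets that did not pass, nor did their mean, at 0.25, adjusted p = 0.233) and CD36 as lower by 1.81 (0.981). None of 8 interferon-induced genes passed (median -1.51, adjusted p = 0.142), the median was -0.09 without MSC_day28 replicate 3 and -0.06 without both arrays with low controls, and RSAD2 was at -1.68 ± 0.82. On MSC_day28 replicate 3, 7 of these 8 genes exceeded both other MSC_day28 arrays by over 1: MX1 read 4.06, 2.62 and 11.17 on replicates 1, 2 and 3. The exception was IFIT2, at 2.06, 2.24 and 2.35. Ribosomal protein genes had a median of -0.15, with none called (0.052), RPSA at -0.44 ± 0.21 included.

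**Figure D3:**
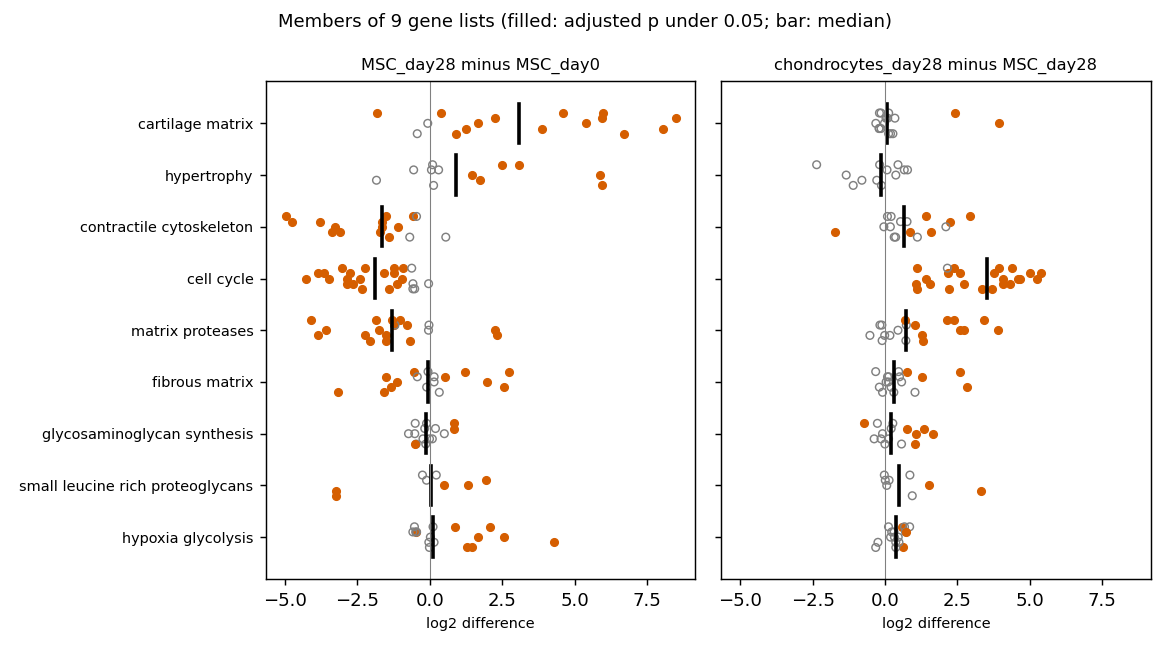
Log2 differences of the members of 9 gene lists in day 28 against day 0 MSCs (left) and in chondrocytes against MSCs at day 28 (right), with filled points for adjusted p under 0.05 and bars for list medians. Cartilage matrix genes had a median of 3.07 at left and 0.07 at right, and cell cycle genes -1.90 and 3.53.

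Chondrocytes at day 28 and MSCs at day 0 differed in both cell source and culture, and this comparison served as the full distance against which day 28 MSCs were placed. Chondrocytes had more SERPINA1 (9.74 ± 0.13, 856-fold), COMP (8.60 ± 0.18), COLGALT2 (8.53 ± 0.26), CHAD (7.85 ± 0.23), SERPINA14 (7.83 ± 0.35) and SMOC2 (7.36 ± 0.24). They had less CCN5 (-6.62 ± 0.46), OLR1 (-6.46 ± 0.26), GRO1 (-6.33 ± 0.73), EEF1A2 (-6.20 ± 0.49), TTR (-5.13 ± 0.46) and the annexin ANXA3 (-5.13 ± 0.26). ACAN was higher by 5.80 ± 0.40, COL2A1, at the end of the scale, by 6.00 ± 0.33, CNMD by 5.60 ± 0.35 and TGFBI by 4.65 ± 0.23, whereas COL1A1 (-0.09 ± 0.18, adjusted p = 0.765) and COL10A1 (0.72 ± 1.00, 0.638) did not pass. In all, 7445 probe sets passed, 3622 higher and 3823 lower in chondrocytes, and 4251 differed at least 2-fold. Centring on ribosomal protein genes, which moved the median of all probe sets by 0.23, gave 5196 higher and 2345 lower, and centring on the array median, which moved it by -0.12, gave 3110 and 5255.

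Cartilage matrix genes were higher in 13 of 16 cases and lower in none, over all genes and adjusted over the list alone (median 4.06, adjusted p = 1.54e-12, and adjusted p = 0.0898 with an estimated correlation). Cell cycle genes were also higher in chondrocytes than in day 0 MSCs, in 18 of 24 cases, 22 adjusted over the list alone, with a median of 1.36 (adjusted p = 4.53e-08, and adjusted p = 0.341 with an estimated correlation). MCM4 was higher by 1.43 ± 0.14, PLK1 by 1.5 ± 0.21 and MCM3 by 1.63 ± 0.22, with a second MCM3 probe set at -0.33 that did not pass. Hypoxia and glycolysis genes were higher in 9 of 17 cases, over all genes and adjusted over the list alone (median 0.480, adjusted p = 0.000355, and adjusted p = 0.339 with an estimated correlation). SLC2A1 was higher by 2.65 ± 0.12, EGLN3, an oxygen-sensing hydroxylase, by 4.77 ± 0.52 and VEGFA by 1.85 ± 0.26. Contractile genes were lower in 11 of 16 cases, over all genes and adjusted over the list alone, where 1 was also higher (median -1.14, adjusted p = 7.71e-05, and adjusted p = 0.339 with an estimated correlation). LMOD1 was lower by 3.46, TPM2 by 3.03 and CNN2 by 2.24. The 3′ to 5′ control difference was larger in chondrocytes than in day 0 MSCs, as given above.

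Among further genes, COL11A2 was higher by 6.82 ± 0.19, WWP2 by 4.67 ± 0.19, THBS4 by 7.35 ± 0.32, ELN by 2.36 ± 0.27, COL12A1 by 2.02 ± 0.13, BGN by 1.97 ± 0.12, PLAUR by 3.59 ± 0.23, PAPSS1 by 1.59 ± 0.19, TEK by 2.19 ± 0.29 and TNNI2 by 2.22 ± 0.29. FABP4 was lower, at -4.64 ± 0.33, as was CXCL12, at -4.94 ± 0.56. ALPL was higher by 4.86 ± 0.84 and PLOD1 by 2.13 ± 0.16, each with a second probe set, at 0.36 and -0.38, that did not pass. PRG4 was at 0.29 ± 0.20 by its probe set of highest mean and did not pass, while its 3 other sets were higher by 6.08, 7.31 and 8.87.

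Hypertrophy genes were higher in 7 of 12 cases and lower in 1 (adjusted p = 0.0226, and adjusted p = 0.341 with an estimated correlation), with PTH1R at 4.55 ± 0.49, ENPP1 at 2.93 ± 0.35 and MMP13 at -2.64 ± 0.76 (a second MMP13 probe set, at -2.31, did not pass). Fibrous matrix genes were higher in 8 of 17 cases and lower in 1 (adjusted p = 0.0303, and adjusted p = 0.341 with an estimated correlation), with POSTN at 5.36 ± 0.55 and COL5A3 at -2.88 ± 0.48. Adjusted over the list alone, the counts were 7 and 1 for hypertrophy and 8 and 2 for fibrous matrix. Without the 2 arrays with low hybridisation controls, neither list passed (medians 0.882 and 0.326, adjusted p = 0.0542 and 0.0776), against medians of 0.906 and 0.264 over all arrays, and 4 rather than 7 hypertrophy genes were higher. Both lists also did not pass with a filter at the 25th percentile of signal (medians 1.46 and 0.44, adjusted p = 0.111 and 0.0986) or centring on ribosomal protein genes (1.14 and 0.49, 0.0829 and 0.0703), and with a filter at the median signal they passed at medians of 1.85 and 0.62 (0.0354 and 0.0382). Among lists that did not pass, the inflammatory genes had a median of -0.81, a mean of 0.07 and an upward test (0.764), and passed with a filter at the median signal (median 2.49, adjusted p = 0.044), with TNFAIP6 higher by 4.65 ± 0.34. In the blood cell list CTSS was lower by 2.27, with a median of -0.15 and a mean of 0.07 (0.895). Medians and means also differed in sign for the endothelial (-0.10 and 0.22, 0.830), adipocyte (0.04 and -0.22, 0.871) and skeletal muscle lists (-0.06 and 0.09, 0.962). MX1 was at -3.66 ± 1.84 (adjusted p = 0.169), and passed without the 2 arrays with low controls (-3.81, 0.0126). Of the ribosomal protein genes RPL10A passed, at -0.43 ± 0.12 (0.0247), and lost its call when arrays were centred on these genes (-0.20, 0.252).

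Of the probe sets that changed in MSCs over 28 days, 4800 changed in the same direction in chondrocytes against day 0 MSCs, 2349 upwards and 2451 downwards. Independent lists of the same sizes would share 529.7 and 596 probe sets, and 50 simulations of unchanged groups gave 0. In these simulations at most 1 probe set was called in a comparison, so that they are no reference for comparisons that hold changes. A smaller number set day 28 MSCs apart from both other groups: 672 probe sets were lower in them than in either, against 234.8 for independent lists, and 440 were higher, against 142.7, with 0 in the simulations. These comparisons share arrays, and 3 arrays cannot be split into groups of at least 2, so that part of each excess may come from the shared arrays. Placed on a scale from day 0 MSCs (0) to chondrocytes (1), the 7445 probe sets called between those groups had a median position of 0.823 in day 28 MSCs (quartiles 0.466 and 1.12, SD of the median over donors 0.0868). The median was 0.994 for 13 cartilage matrix genes, 1.30 for 11 contractile genes, where values over 1 lie beyond chondrocytes, and -1.48 for 18 cell cycle genes, where day 28 MSCs lay on the far side of day 0 MSCs. Of these 7445 probe sets, 1297 (17.4%) also differed between chondrocytes and day 28 MSCs in the same direction, and 283 differed in the opposite direction. The positions are descriptions only. The day 0 MSC arrays enter both parts of the ratio, and the probe sets were picked by its lower part, so that the ratios are biased.

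**Figure D4:**
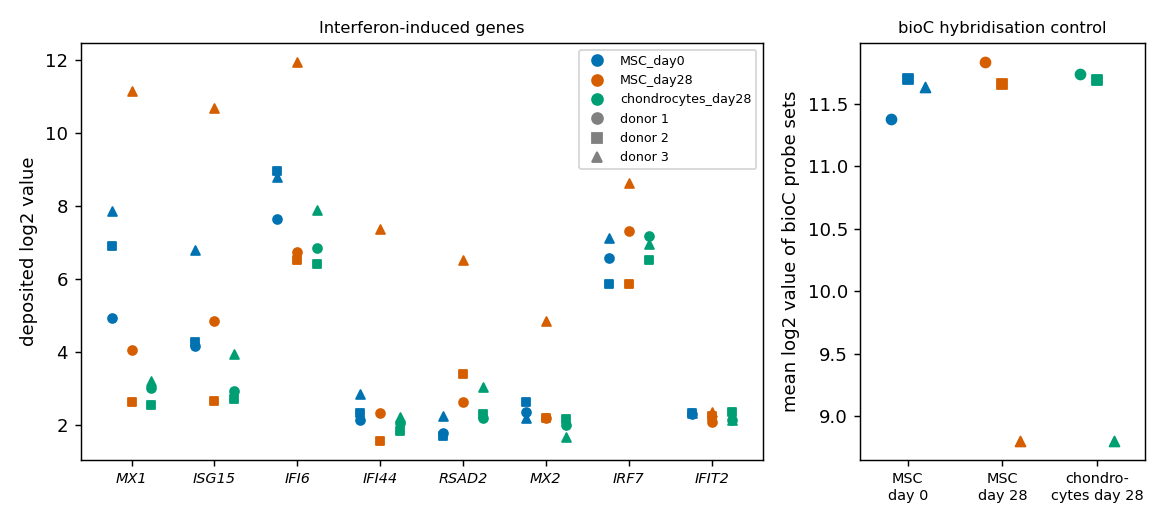
Deposited log2 values of 8 interferon-induced genes in each array (left) and the mean log2 value of the bioC hybridisation control probe sets per array (right), with colour for the group and shape for the donor. MX1 read 11.17 on MSC_day28 replicate 3, and bioC averaged 8.80 on that array and chondrocytes_day28 replicate 3, against 11.66 on the other 7.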

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

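All tests in this part were chosen after the results had been seen, except that of the PRG4 and TPR deviations, whose differences between groups had been seen first.

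The hybridisation control bioC, which no comparison uses, differed by -2.858 between the mean of MSC_day28 replicate 3 and chondrocytes_day28 replicate 3 and that of the other 7 arrays (8.80 against 11.66, with a range of 11.38 to 11.83 on the 7). The controls bioB (-1.49), bioD (-0.80) and cre (-0.39) were lower as well. The labels name no batch, and these 2 arrays are called a hybridisation batch here only from their controls. With the batch as a block, 7180, 3069 and 7329 probe sets passed in the 3 comparisons, and without the arrays 6322, 1895 and 6618.

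Cell cycle genes were higher in chondrocytes than in MSCs at day 28 in 23 of 24 cases, with a median of 3.53 (adjusted p = 2.16e-31, and adjusted p = 0.134 with an estimated correlation). The 2 arrays with low hybridisation controls lay on both sides of this comparison, so that a shift common to both would cancel. Without them the median was 3.85. The difference was thus present on the other arrays of these groups as well, which is all that leaving them out can show. Centring on ribosomal protein genes moved all probe sets by the same 0.163 and gave a median of 3.689. It shows only that a constant shift between arrays, as these genes measure it, was small beside 3.53. On other forms of scaling it cannot decide. RNA quality as the mean of 5 control transcripts shows it is argued against: the 3′ minus 5′ difference averaged 1.87 and 1.86. A difference of -0.504 with a slope within groups of -2.3, the pair inside their 95% intervals that accounts for most, would give 1.16 of the median. Single control transcripts differed in direction between these groups, with gapd at -0.63 and eIF4E at 0.47, and no such limit was computed for each. The design's own explanation, that chondrocytes and MSCs divided at different rates after 28 days, may hold as a hypothesis. Neither the share of dividing cells nor chondrocytes at day 0 were measured, and culture history before embedding stays open and untested.

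Interferon-induced genes were higher on MSC_day28 replicate 3 than on the other MSC_day28 arrays, by 4.24 on average over 8 genes, 8 of 8 of them highest there and 7 above both other arrays by over 1. The hybridisation batch as the cause is argued against by chondrocytes_day28 replicate 3, whose excess was 0.44. An effect of donor 3 of like size in every culture is argued against by that array and by MSC_day0 replicate 3, at 0.844. On each of these donor 3 arrays, 5 of 8 genes still lay above both other arrays of the group. A smaller contribution of donor 3 thus stays open. The blood cell list had a median excess of 0.037 on that array, which shows no broad rise of these markers. Some of them lay at low signal, such as AIF1 and TYROBP, with means of 2.136 and 2.426 in day 28 MSCs. A small share of blood cells in that culture therefore stays open. A response of that culture alone, for example to infection, may remain as a hypothesis that was not tested, and the design names no difference between the cultures of this group but the donor.

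Probe sets of the same name differed between chondrocytes and day 28 MSCs by unequal amounts, with the 2 TPR sets at 7.93 and -0.25 and the 4 PRG4 sets from -0.01 to 7.88. The genes overlap at their ends in the annotation, so that a TPR probe set may measure PRG4 transcripts. A first test on these differences was dropped as circular, and in the second the discordant TPR set's deviations from its group means correlated with those of the 3 discordant PRG4 sets at 0.702 over 9 arrays, the 93.2 percentile of all probe sets, which lay below the bound set for that explanation. They correlated with the other TPR set at 0.945, and that set stood at the 98.3 percentile, so that the sources cannot be told apart by deviations of 9 arrays that share their donors, and no sequence of a probe was used here. The discordant TPR set shares the stem of its probe set name with the 3 discordant PRG4 sets, and the other TPR set does not. Nor does the PRG4 set of highest mean, which stood for the gene in the list tests. Its deviations correlated with those of the 3 discordant PRG4 sets at -0.581, the 14.7 percentile, and whether it measures PRG4 was not tested. In day 0 MSCs, day 28 MSCs and chondrocytes the discordant TPR set averaged 2.49, 3.815 and 11.74. A discordant PRG4 set averaged 2.53, 3.524 and 11.4, the PRG4 set of highest mean 9.309, 9.608 and 9.597, and the other TPR set 7.177, 7.505 and 7.255. These means were seen first and are no test.

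For the counts of called probe sets, 10 splits of 6 arrays are too few for a share under 0.05. The real split gave 7256 for MSC_day28 minus MSC_day0, 2482 for chondrocytes_day28 minus MSC_day28 and 7445 for chondrocytes_day28 minus MSC_day0, 1 of 10 splits in each case, and the highest of the other splits gave 0.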

How the results depend on the processing

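The batch block and the fit without the 2 arrays with low hybridisation controls were chosen after the data had been seen, and all other alternatives before. Apart from leaving out arrays in turn, 979 values of 66 list results kept their side of the threshold, 44 passed only there and 33 no longer passed, and 0 turned direction. For named genes 2040 kept their side, 15 passed only there, 23 no longer passed and 2 turned. The 2 were PRG4 in chondrocytes_day28 minus MSC_day28, at 5.0 with the mean of its probe sets and 7.88 with the set of largest SD, because its probe sets differ. Values that passed neither in the fit used for the results nor under the alternative changed sign in 73 list and 16 gene cases. These counts include the fits that left out arrays or donors. In chondrocytes_day28 minus MSC_day28 the genes were PRG4 (-0.245 to 7.88 over all alternatives), COL2A1 (-0.08 to 0.34) and COMP (-0.08 to 0.40). In chondrocytes_day28 minus MSC_day0 the gene was COL1A1 (-0.228 to 0.143).

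Stricter thresholds lower counts by construction. An adjusted p under 0.01 gave 4486, 1063 and 4386 probe sets (MSC_day28 minus MSC_day0, chondrocytes_day28 minus MSC_day28, chondrocytes_day28 minus MSC_day0), with 122 higher and 302 lower in day 28 MSCs than in both other groups and 2738 changed in the same direction in both day 28 groups. A 2-fold change in addition to 0.05 gave 4231, 1475 and 4251, with 172, 389 and 2658. Counts by gene test fewer features: the mean of probe sets gave 3293, 1372 and 3482 with 216, 385 and 2182, the set of highest mean 3295, 1380 and 3460 with 209, 410 and 2171, and the set of largest SD 3385, 1298 and 3594 with 192, 393 and 2283. Centring on ribosomal protein genes gave 289 probe sets higher in day 28 MSCs than in both, and a trended and robust variance gave 10 lists in chondrocytes_day28 minus MSC_day0, against 6; the cause was not tested. An estimated correlation gave 0, 0 and 0 lists, against 5, 7 and 6, and fry, which does not compare a list with other genes, 12, 11 and 14.

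With the donor as a block, 8070, 3110 and 8247 probe sets passed, of which 7070, 2357 and 7240 were shared with the fit without it. Of the named genes RSAD2 in MSC_day28 minus MSC_day0 and NFIB in chondrocytes_day28 minus MSC_day28 passed only with the block, and it changed no other named gene call.

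Leaving out an array or a donor gave 4292 to 7010, 747 to 2598 and 3344 to 7794 probe sets, 5 to 6, 6 to 9 and 4 to 8 lists, and 87 to 485 higher, 240 to 642 lower and 2196 to 4547 changed alike. The position ranged from 0.763 to 0.863. In these fits 87 named gene and 11 list values no longer passed and 6 and 18 passed only there. Without donor 1 the counts were 4292, 747 and 3344, with 87, 279 and 2196, and without donor 2 they were 4574, 766 and 4963, with 96, 240 and 3085. Without donor 3, 1520 probe sets passed in chondrocytes_day28 minus MSC_day28, with 227 and 387. Without MSC_day28 replicate 2, 293 were higher in day 28 MSCs than in both, and without chondrocytes_day28 replicate 1, 292. Without chondrocytes_day28 replicate 2, 1356 passed in chondrocytes_day28 minus MSC_day28, with 189 and 398. Of 150 named gene results, 19 lost their call without donor 1, 14 without donor 2 and 7 without donor 3, and 4 to 8 without a single array.

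Calls near the threshold depended on single arrays. In MSC_day28 minus MSC_day0, COL1A1 did not pass without MSC_day0 replicates 1, 2 or 3 (0.0896, 0.0863, 0.115), MSC_day28 replicates 2 or 3 (0.134, 0.0884) or chondrocytes_day28 replicate 2 (0.0644), and COL10A1 not without MSC_day0 replicates 1, 2 or 3 (0.101, 0.0934, 0.108), MSC_day28 replicate 3 (0.054) or any chondrocyte array (0.0614 to 0.0666). RSAD2 passed without MSC_day28 replicates 1 (0.019) or 3 (0.0347). In chondrocytes_day28 minus MSC_day28, the glycosaminoglycan list did not pass without MSC_day28 replicate 3 (0.0575) or chondrocytes_day28 replicate 1 (0.0545), the hypoxia list not without MSC_day28 replicate 1 (0.0623), and the interferon list passed, as lower, without MSC_day28 replicates 1 (0.0409) or 2 (0.013). The blood cell list passed in MSC_day28 minus MSC_day0 without MSC_day0 replicate 3 (0.00622). In chondrocytes_day28 minus MSC_day0, the fibrous matrix list did not pass without MSC_day0 replicate 1 (0.0548) or chondrocytes_day28 replicate 3 (0.0642), and MX1 passed without MSC_day28 replicate 3 (0.004). In chondrocytes_day28 minus MSC_day28, PGAM1 did not pass without any array but MSC_day28 replicate 2 (0.0553 to 0.154), TIE1 without MSC_day0 replicate 1, any MSC_day28 array or chondrocytes_day28 replicates 1 or 2 (0.0515 to 0.117), ENO1 without MSC_day28 replicate 2 or chondrocytes_day28 replicates 1 or 2 (0.0584 to 0.0728), COL6A1 without MSC_day28 replicate 1 or chondrocytes_day28 replicates 2 or 3 (0.0516 to 0.063), LIPE without MSC_day28 replicates 1 or 2 or chondrocytes_day28 replicate 2 (0.0561 to 0.0693), and OPTC (0.0506) and SLC2A1 (0.0507) without chondrocytes_day28 replicate 1. RPL10A in chondrocytes_day28 minus MSC_day0 did not pass without any MSC_day0 or chondrocyte array (0.0555 to 0.0735). Low signal over background compresses differences, so that a gene not called at low signal was not shown to be unchanged.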

Other observations

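The lists in this part were written after the main results had been seen, over 12 tests, and genes whose values had been seen were left out; the test of the amino acid stress genes was also chosen after its result was seen.

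Immediate early genes, which are induced within minutes by stimuli such as handling or serum, were tested as a list. FOSB had been seen to fall in MSCs over 28 days and was left out. Of the 13 others, 8 fell, 9 adjusted over the list alone, with a median of -0.962 (camera adjusted p = 0.0017, and adjusted p = 0.0716 with an estimated correlation). NR4A1 was at -2.50 ± 0.21, EGR1 at -2.31 ± 0.31, DUSP1 at -2.26 ± 0.39 and FOS at -1.24 ± 0.37. In chondrocytes against day 28 MSCs, 2 of the 13 were higher, FOSL1 (1.30 ± 0.32) and JUNB (0.68 ± 0.15), and 11 were not called, with 5 higher and 1 lower adjusted over the list alone and a median of 0.719 (adjusted p = 0.00353, and adjusted p = 0.0716 with an estimated correlation). Against day 0 MSCs, 4 were lower in chondrocytes, with a median of -0.393, and the list did not pass (adjusted p = 0.165, and adjusted p = 0.385 with an estimated correlation). The fall of the class rests on the preset correlation, and what caused it, a response to isolation and embedding before the day 0 harvest included, was not tested.

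Genes induced by amino acid shortage were tested between chondrocytes and day 28 MSCs. SESN2 (-2.04 ± 0.26), NUPR1 (-2.22 ± 0.20), DDIT4L and DDIT3 had been seen to be lower and were left out. Of the 16 others 3 were lower, PSPH (-1.12), VLDLR (-1.0) and SARS1 (-0.96), and 13 were not called, with 7 lower adjusted over the list alone, with a median of -0.523 (adjusted p = 0.00353, and adjusted p = 0.385 with an estimated correlation). Against day 0 MSCs, 9 of the 16 were lower and 2 higher in chondrocytes (median -0.707, adjusted p = 0.0241, and adjusted p = 0.446 with an estimated correlation). In MSCs over 28 days 3 rose and 2 fell (median -0.295, adjusted p = 0.574, and adjusted p = 0.762 with an estimated correlation). The list's calls were thus lost with an estimated correlation, and no cause was tested.

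C3 was lower in chondrocytes than in day 28 MSCs, and 13 complement genes not seen before were tested as a class. Of these, CFI (2.24) and SERPING1 (2.21) were higher and 11 were not called. The median was 0.089, and the list test pointed up without passing (adjusted p = 0.165, and adjusted p = 0.446 with an estimated correlation). By the criterion written before the test, a median that was not negative counted against a lower class. The standard error of 0.161 was brought in after the values were known, and it leaves the sign of the median uncertain. TYROBP, CD68 and AIF1 fell in MSCs over 28 days, and 12 further macrophage genes had a median of -0.199 (adjusted p = 0.574, and adjusted p = 0.724 with an estimated correlation). C1QA (-1.67 ± 0.50, adjusted p = 0.0321) and ITGB2 (-1.33 ± 0.42, 0.0404) fell, HCLS1 rose by 5.30 ± 0.42, and 9 were not called. Both falls lay at low signal, from 3.20 to 1.54 for C1QA and from 3.37 to 2.04 for ITGB2. Of the 12, 10 had negative values, some close to no change, such as ITGAM (-0.019) and LGMN (-0.0012). Macrophages in the day 0 cultures thus cannot be told apart from other sources of these transcripts.

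Some lists that did not pass passed under an alternative chosen in advance. In chondrocytes_day28 minus MSC_day28, ribosomal protein genes passed with centring on the array median (0.0257), a trended and robust variance (0.00167) or each of 3 gene-level values (0.0292 to 0.0449), interferon-induced genes when arrays were centred on ribosomal protein genes (-1.35, 0.0432), articular surface genes with the mean of probe sets (0.0488), and secretory pathway genes with the trended and robust variance (0.0397). In chondrocytes_day28 minus MSC_day0, ribosomal protein genes passed with centring on the array median (0.0363), small leucine-rich proteoglycans with the mean of probe sets (0.0452), and articular surface genes (0.0368) and TGF-beta signalling genes (0.0442) with centring on the array median. Some lists passed with 1 array left out. In chondrocytes_day28 minus MSC_day0 these were articular surface genes without MSC_day0 replicate 2 (0.032), MSC_day28 replicate 3 (0.0396) or chondrocytes_day28 replicate 1 (0.0369), secretory pathway genes without MSC_day0 replicate 2 (0.0412) or chondrocytes_day28 replicate 1 (0.0369), and TGF-beta signalling genes without MSC_day0 replicate 1 (0.0475). In chondrocytes_day28 minus MSC_day28 they were secretory pathway genes without MSC_day28 replicate 2 (0.0144), TGF-beta signalling genes without MSC_day28 replicate 1 (0.05) and ribosomal protein genes without MSC_day28 replicate 3 (0.0396). Hypoxia genes passed in MSC_day28 minus MSC_day0 without MSC_day28 replicate 1 (0.0389). Among single genes, OMD passed in chondrocytes_day28 minus MSC_day28 without MSC_day28 replicate 1 (0.0244), SLC2A1 did not pass there without chondrocytes_day28 replicate 3 (0.05), and MYL11 did not pass in MSC_day28 minus MSC_day0 without replicate 2 of MSC_day0 (0.0632) or of MSC_day28 (0.061).

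Other calls ended when a donor was left out, which leaves fewer arrays. In chondrocytes_day28 minus MSC_day28 these were FLNA (0.0603), CTSS (0.0772), ITGA5 (0.0826) and P4HA3 (0.0585) without donor 1, ACTA2 (0.0664) and BPNT2 (0.0592) without donor 2, and COL6A2 without donors 2 (0.0981) or 3 (0.0708). COL6A1 (0.133 and 0.166), ENO1 (0.194 and 0.206), LIPE (0.141 and 0.179), OPTC (0.162 and 0.105), TIE1 (0.266 and 0.273) and TNNI2 (0.085 and 0.136) did not pass there without donors 1 or 2, and PGAM1 (0.0702 to 0.308) and SLC2A1 (0.0761 to 0.176) with any 1 donor left out. COL1A1 (0.0639 to 0.255) and MYL11 (0.0542 to 0.0815) in MSC_day28 minus MSC_day0 and RPL10A (0.0877 to 0.163) in chondrocytes_day28 minus MSC_day0 did not pass with any 1 donor left out, and COL10A1 in MSC_day28 minus MSC_day0 not without donors 1 (1.68, 0.088) or 3 (3.35, 0.156). Among lists, glycosaminoglycan synthesis in chondrocytes_day28 minus MSC_day28 did not pass without donors 1 (0.0771) or 3 (0.0691), fibrous matrix in chondrocytes_day28 minus MSC_day0 without donors 2 (0.0627) or 3 (0.0536), and hypertrophy there without donor 3 (0.0587). Not called over all arrays but past the threshold then were blood cell genes in MSC_day28 minus MSC_day0 without donor 3 (0.015), interferon-induced (0.025) and secretory pathway genes (0.0246) in chondrocytes_day28 minus MSC_day28 without donor 2, TGF-beta signalling genes without donor 1 in that comparison (0.0476) and in chondrocytes_day28 minus MSC_day0 (0.0445), and, without donor 3, RSAD2 in MSC_day28 minus MSC_day0 (1.29, 0.02) and MX1 in chondrocytes_day28 minus MSC_day0 (-3.16, 0.0253).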
